A study of Bos taurus with 18 samples.

How the data were processed

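Total RNA of 18 pools of 60 blastocysts each, collected on day 7, was amplified from 50 ng and hybridised to Affymetrix bovine arrays, per the labels' protocols. The deposited values are log2 expression values per probe set, and the submitters' processing notes name RMA and Partek 6.4 without saying what each did. The log2 scale was read from the values, which lie between 1.89 and 14.15 among the tested probe sets. RMA draws the arrays' distributions together, so that a shift of all transcripts between groups cannot be seen, and summarised probe signals understate large differences of dim transcripts. Scan dates and batches are not given in the sources used here.

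Array control probe sets (112) were left out, and 24016 of 24128 probe sets were tested. GEO's platform annotation lists 1 gene for 13292 of them, several for 86 and none for 10638. Symbols were updated by gene number through a table of the assembly ARS-UCD2.0, used only for names and chromosomes, where 13263 matched and 29 did not. This gave 396 X-linked, 12 Y-linked and 12827 autosomal probe sets and 9155 genes.

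Groups and tests were fixed before the data were examined, apart from tests of lists on the interaction and others named below as added later. Means of the 6 groups of sex and bull were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom), with contrasts for sex averaged over bulls, sex within each bull, the interaction and the bulls. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are 2 to the power of the log2 difference. Lists of genes (28, of which 26 had at least 5 measured genes) were tested with camera on the brightest probe set per gene with a preset correlation of 0.01, and again with an estimated correlation, and with fry. The X-linked share was tested by Fisher's exact test. The Y-linked list (2 genes) and the interferon tau list (1 gene) were too small.

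Genes were named by a rule: the 12 largest differences per direction for sex with the same sign in all 3 bulls, 8 per direction on the X chromosome, 4 per direction for each pair of bulls with the same sign in both sexes, XIST and the measured Y-linked genes, and up to 4 members per list with the smallest p. Only probe sets with 1 listed, non-provisional gene were named, with exceptions stated where they occur.

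The steps were tested on simulated data with 24016 probe sets, each with its residual spread over the real arrays. The noise was normal, independent between probe sets and equal on all arrays, whereas 4 real arrays had a wide spread. The shares below hold for that simpler setting. For the sex contrast, 93% of 100 changes of 0.6 log2 and 31% of 100 changes of 0.3 log2 were recovered, with 7 false among 131 calls. For the interaction test, 86% of 100 changes of 1.2 log2 and 25% of 100 changes of 0.6 log2 were recovered, and for bull 2 against bull 1, 88% of 100 changes of 0.6 log2. Alternatives were an additive model, analysis of variance without moderation, the brighter 50% of probe sets, repeated quantile normalization, an intensity trend, array weights, 1 probe set per gene, the sample number as a block, leaving out each bull or array, bull as the replicate, the arrays of 1 bull alone, and the mean over a gene's probe sets. Leaving out 4 arrays whose relative spread exceeded 0.25, and the 5′ to 3′ index as a covariate, were added after seeing the data. Figures were drawn with matplotlib.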

Results

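RNA from bovine blastocysts collected 7 days after insemination in vitro was measured on 18 Affymetrix bovine arrays. The embryos came from sex-sorted semen of 3 bulls, and each array held RNA of a pool of 60 blastocysts of 1 sex from 1 bull. Each of the 6 groups of sex and bull had 3 arrays, so that 9 arrays of females stood against 9 of males. The values were log2 expression values of 24016 probe sets, with array medians from 5.33 to 5.49. Array data give no read depth, and the number of arrays limits the precision. The labels do not say whether the 3 pools of a group came from separate fertilisation runs, and the p-values measure only the spread between these pools.

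XIST, the RNA that coats the inactive X chromosome, separated the sexes on every array. Its brightest probe set had a log2 value of 9.21 ± 0.23 in females and 6.63 ± 0.50 in males (SD, n = 9 arrays each), a 5.97-fold difference, with females from 8.87 to 9.57 and males from 5.93 to 7.28. The Y-linked TSPY and ZFY did not pass the test. The brightest TSPY probe set had means of 6.96 ± 0.11 in females and 6.94 ± 0.18 in males, and ZFY had 2.25 ± 0.13 and 2.25 ± 0.04. The group means of XIST in females were 9.38, 9.17 and 9.07 for bulls 1, 2 and 3, and those in males were 6.86, 6.07 and 6.96. A Y-linked probe set of the provisional gene LOC100335202, named after its values were seen, was higher in males by 2.04-fold. The probe set with the largest difference of all has no gene listed and was also singled out after its values were seen. It stood at 7.55 ± 0.36 in males and 3.96 ± 0.49 in females, 12.02-fold higher in males.

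**Figure D1:**
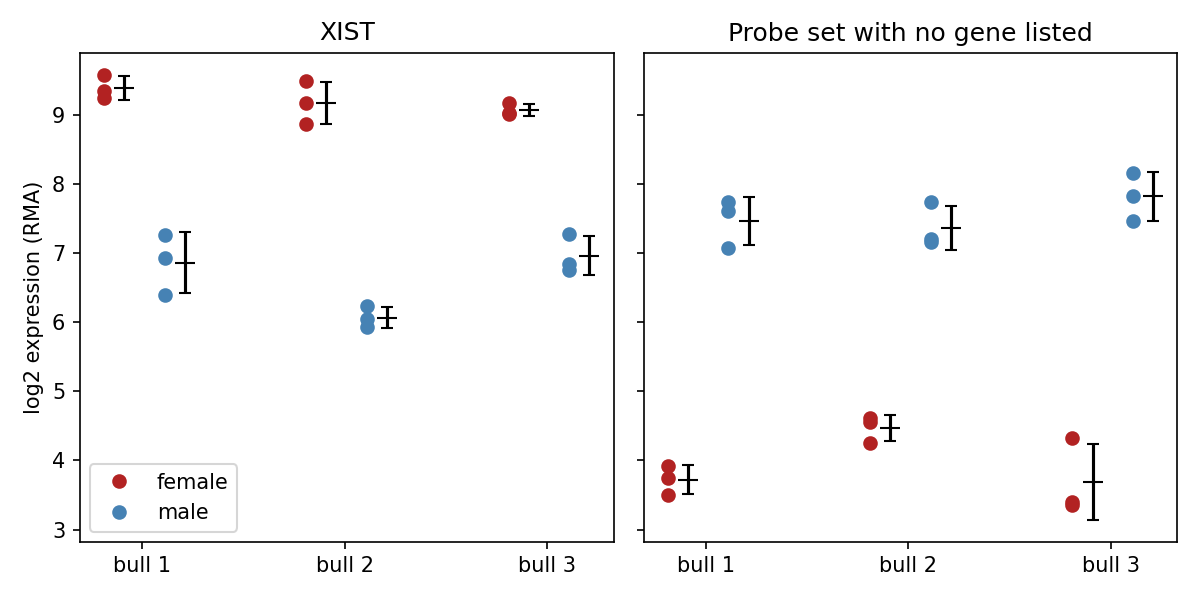
Log2 expression of XIST (left) and of the probe set with no gene listed (right) on each array, by bull and sex, with points for single arrays and black marks for the mean and SD of 3 arrays. XIST lies from 8.87 to 9.57 in females and from 5.93 to 7.28 in males, and the unnamed probe set has means of 3.96 in females and 7.55 in males.

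The main question was which transcripts differ between female and male blastocysts. After XIST, the named genes highest in females were GSTM3, a glutathione transferase, at 7.05 ± 0.29 against 5.07 ± 0.32 in males (3.94-fold, n = 9), and PRM1, the sperm nuclear protein protamine 1, at 6.65 ± 0.18 against 4.92 ± 0.39 (3.32-fold). The X-linked FMR1NB, BEX4, BEX3, SAT1, PAGE4 and TMSB15B were higher in females by 3.10, 3.02, 2.80, 2.73, 2.45 and 2.44-fold. PLET1, HSPA1A, a heat shock protein, and CKM, the muscle creatine kinase, were higher by 2.76, 2.68 and 2.67-fold. HSPA1A is uncertain, because it has near-identical copies, and of 6 probe sets listed for it 3 passed (1.42, 1.22 and 1.15 log2) and 3 did not (0.12, -0.03 and -0.11). Differences toward males were smaller. CHPT1, an enzyme of phosphatidylcholine synthesis, stood at 7.84 ± 0.46 in males and 6.91 ± 0.40 in females (1.90-fold), and FADS2, a fatty acid desaturase, at 9.03 ± 0.19 and 8.20 ± 0.23 (1.78-fold). BPHL, SLC9A3, P2RX4, VPS4A, SLC6A20, SH3YL1 and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, were higher in males by 1.66 to 1.76-fold. The histone genes H4C2 and H2BC19 (1.71 and 1.68-fold) and PAG2, a pregnancy-associated glycoprotein (1.60-fold), belong to families of similar genes and are uncertain. The rule that named these genes took the probe set with the largest difference and required the same direction in all 3 bulls. Other probe sets gave 0.45 log2 for PLET1, -0.07 for CKM, -0.08 for BPHL, 0.02 for each of the 2 of SLC9A3 and -0.20 for VPS4A, of which PLET1 passed and that of VPS4A was the brighter.

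In limma's test with Benjamini-Hochberg adjustment, 3743 of 24016 probe sets (15.59%) differed between the sexes, 1950 higher in females and 1793 higher in males. Most differences were small, with a median absolute size of 0.32 log2. Of those at or above 2-fold, 81 were higher in females and 3 in males. PAG2 no longer passed without bull 2 (adjusted p = 0.08) or without bull 3 (adjusted p = 0.068).

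Within single bulls, females and males differed at 1008 probe sets for bull 1, 752 for bull 2 and 1004 for bull 3, of which 657, 618 and 637 were higher in females. Leaving out 1 array moved these counts to 625 to 1240, 422 to 956 and 465 to 1317, each lowest without 1 female array of that bull, replicate 3, 2 and 3 in turn. GSTM3 was higher in females by 1.92, 1.88 and 2.14 log2 in bulls 1, 2 and 3, PRM1 by 1.71, 1.71 and 1.77, and SAT1, the enzyme that acetylates spermidine and spermine, by 1.42, 1.42 and 1.5. FADS2 differed by -0.80, -0.78 and -0.90 log2 in the same order. When the 6 arrays of a bull were fitted alone, 290, 942 and 596 probe sets passed, and 98.28%, 96.39% and 97.82% of them had the same sign in both other bulls. Signs that are random and independent between bulls would give 25%. Across all probe sets, which are not independent replicates, the sex differences of 2 bulls correlated at r = 0.649 to 0.654. Of all probe sets, 65% to 65.8% had the same sign in 2 bulls.

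No probe set was called for a sex difference that itself differed between bulls. Such differences can be missed, since the test recovered 25% of 100 changes of 0.6 log2 simulated with noise equal on all arrays. The called sex differences themselves had a median absolute size of 0.319 log2. The interaction test of limma called 0 of 24016 probe sets, with 656 (2.73%) at an unadjusted p under 0.05, and the analysis of variance without moderation also called 0. XIST had sex differences of 2.52, 3.10 and 2.11 log2 in bulls 1, 2 and 3, and SLC6A20 of -0.76, -0.45 and -1.01, and neither passed the test of a difference between bulls.

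Genes on the X chromosome were mostly higher in females. Of 396 X-linked probe sets, 252 (63.64%) were higher in females, against 989 of 12827 autosomal ones (7.71%), an odds ratio of 20.9 (95% confidence interval 16.8 to 26.1, Fisher's exact test, two-sided, p = 3.81e-164). The interval and p treat probe sets as independent, although several can belong to 1 gene and genes vary together. Camera with an estimated correlation gave p = 7.7e-05 for 297 X-linked genes, on the brightest probe set of each. Of 256 X-linked probe sets that differed, 98.44% were higher in females, against 47.85% of 2067 autosomal ones. The median X-linked probe set was 0.39 log2 higher in females, and among the brighter 50% of probe sets 0.53 log2, or 1.44-fold, while the autosomal median was -0.03. The 8 X-linked genes with the largest differences were XIST, FMR1NB, BEX4, BEX3, SAT1, PAGE4, TMSB15B and SRPX2 (2.43-fold, and 0.51 log2 in its brighter probe set). Only 4 X-linked probe sets were higher in males. CD99, a cell surface protein, had 2 of them, at 8.58 ± 0.14 in females and 8.93 ± 0.21 in males for the one with the larger difference. The others were dim probe sets of PDHA1 and KDM6A, whose brightest probe sets were higher in females by 0.39 and 0.70 log2. The dim PDHA1 probe set lost its call without bull 1, without bull 2 and without 4 arrays of wide spread (adjusted p = 0.0872, 0.0829 and 0.0965). That of KDM6A, at an adjusted p of 0.0496, lost it without each of the bulls (0.0679 to 0.504), without these 4 arrays (0.0555), in 13 of 18 fits without 1 array (0.0553 to 0.109), with the sample number as a block (0.0778) and in 5 other fits, among them quantile normalization (0.102) and bull as the replicate (0.136).

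**Figure D2:**
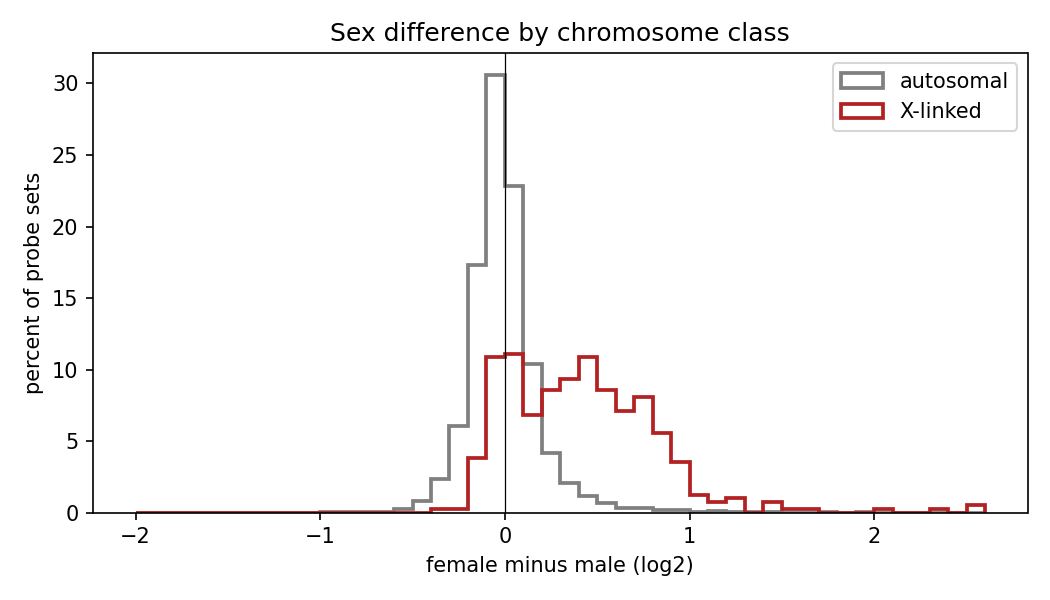
Distribution of the female minus male difference (log2, horizontal axis) as percent of probe sets (vertical axis) for 12827 autosomal and 396 X-linked probe sets. The autosomal differences centre near -0.03 and the X-linked ones near 0.39.

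Both lists of X-linked genes rose in females. Of 20 measured genes that escape X inactivation in human, 17 were higher in females and none in males (17 when adjusted over the list alone), among them TRAPPC2 (1.02 log2), MSL3 (0.93), AP1S2 (0.81) and UBA1, the ubiquitin-activating enzyme (0.60). Of 54 other X-linked genes, 49 were higher in females (51 when adjusted over the list alone), with SAT1, BEX4, CITED1 (0.90) and MAGED1 (0.69) among those of smallest p. Both calls held with an estimated correlation between genes (adjusted p = 0.00136 for each).

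A further 2 lists, both of autosomal genes, passed in camera's test with the preset correlation and not with an estimated one. Of 72 nuclear genes of oxidative phosphorylation, 11 were higher in males and 1 in females (12 and 1 when adjusted over the list alone), with NDUFS1 at -0.36 log2, UQCRC1 at -0.26, SDHA at -0.22 and NDUFC1 at -0.20. The list's median sex difference was -0.162, -0.102 and 0.011 log2 in bulls 1, 2 and 3. In a camera test not among those planned, it differed between bulls 3 and 1 with the preset correlation (adjusted p = 2e-10, and adjusted p = 0.936 with an estimated correlation). The mean 5′ minus 3′ signal of 3 control transcripts, read here as a sign of RNA integrity, differed between the sexes. Females minus males gave -0.22, 0.01 and 0.22 log2 in these bulls. The gaps in bulls 1 and 3 rest on 1 male array each. Male bull 1 replicate 2 stood at 0.447, against -0.347 and -0.06 in the other males of that bull. Male bull 3 replicate 3 stood at -1.268, against -0.575 and -0.566. For sex over all bulls, the adjusted p of the list was 0.000271, and 0.895 with an estimated correlation. Of 15 genes of cholesterol synthesis, 6 were higher in males and none in females (7 when adjusted over the list alone), with the regulator SREBF2 at -0.61 log2, CYP51A1 at -0.49, FDFT1 at -0.30 and DHCR7 at -0.24. That list had an adjusted p of 0.000727, and of 0.895 with an estimated correlation. In 55 of 100 splits of the arrays, the real one included, at least 4 lists passed with the preset correlation, so that the number of lists called does not exceed what other splits gave. Without 1 of the bulls UQCRC1, SDHA, NDUFC1, FDFT1 and DHCR7 lost their calls (adjusted p = 0.0635 to 0.12), as did NDUFC1 with bull as the replicate (0.0935).

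In fry's test, which asks whether the genes of a list move on balance one way without setting them against other genes, both passed (adjusted p = 0.0288 for oxidative phosphorylation and 0.00619 for cholesterol synthesis), as did both X-linked lists, imprinted genes (0.00562) and antioxidant genes (0.0223). Camera called neither imprinted genes (adjusted p = 0.367) nor antioxidant genes (adjusted p = 0.332), with 0.895 for each with an estimated correlation.

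The other 22 tested lists did not pass camera's test, though single members did, and counts adjusted over the list alone follow in brackets where they differ. Over the whole array, 3743 of 24016 probe sets (15.59%) differed by sex, and with 1 probe set per gene 2222 of 9155 genes. Counts of list members here and below were not tested against these shares, so no count alone sets a list apart. Among 22 trophectoderm markers 2 were higher in females and 5 in males, with SSLP1 at 0.75 log2 and PAG2, PAG11 and ASCL2 at -0.68, -0.48 and -0.42. Among 8 markers of the inner cell mass 2 were higher in females, STAT3 (0.28) and SPP1 (0.56), and among 19 of the primitive endoderm 4 were higher in females and 2 in males (5 and 2 adjusted over the list alone), with RBP4 at 0.92 and P4HA2 at -0.37. IFNT2, the only measured interferon tau gene, was 1.5-fold higher in females, at 11.15 ± 0.21 against 10.56 ± 0.31. Its difference was 0.96, 0.45 and 0.35 log2 in bulls 1, 2 and 3. Like PAG2, it belongs to a family of similar genes and is uncertain. Among 24 genes of blastocoel formation AQP3 was higher in females (0.39), and AQP11 (-0.53), CDH1 (-0.18) and DSC2 (-0.42) were higher in males. Without 1 of the bulls PAG2, PAG11, ASCL2, STAT3, SPP1, P4HA2, CDH1 and DSC2 lost their calls (adjusted p = 0.0548 to 0.301), as did CDH1 with bull as the replicate (0.0959) and SPP1 and DSC2 without moderation (0.0547 and 0.0832). DSC2 also lost it in 7 of 18 fits without 1 array (0.0543 to 0.0709).

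Among 24 imprinted genes 6 were higher in females and 1 in males. PHLDA2, a placental growth regulator, stood at 8.21 ± 0.23 in females and 7.02 ± 0.19 in males (2.28-fold), PEG10 was higher by 1.93-fold and PEG3 by 1.33-fold, and SNURF was higher in males (-0.26 log2). Among 29 antioxidant genes 7 were higher in females and 3 in males, with the X-linked PRDX4 at 0.75, GSTO1 at 0.52 and SOD1 at 0.46 log2 after GSTM3. Of 24 heat shock genes DNAJB1 (0.63) and HSPA1A were higher in females and HSPA9 (-0.19) in males. In apoptosis, 2 of 19 were higher in females, CDKN1A (0.57) and BAK1 (0.22), and 3 in males, among them BCL2 (-0.21) and MDM2 (-0.28), with 3 and 3 adjusted over the list alone. EZH2, a histone methyltransferase, was higher in females (0.38) and EHMT1 (-0.19) and CBX3 (-0.15) in males among 26 histone modifiers. Among 13 genes of DNA methylation, DNMT3A was higher in males (-0.33) and the X-linked ZBTB33 in females (0.29). Of 20 glycolytic genes 3 were higher in females, with ALDOC at 0.85 and PFKM at 0.45, and 2 in males, SLC2A8 at -0.35 and SLC2A5 at -0.17 (3 and 3 adjusted over the list alone). Without 1 of the bulls SNURF, HSPA9, BAK1, BCL2, MDM2, EHMT1, CBX3, DNMT3A, ZBTB33, PFKM and SLC2A5 lost their calls (adjusted p = 0.0634 to 0.489), as did HSPA9, BAK1, BCL2, EHMT1, CBX3 and SLC2A5 with bull as the replicate (0.0701 to 0.161), ZBTB33 without moderation (0.0884), and EHMT1 and CBX3 without 4 arrays of wide spread (0.0733 and 0.0674). Of 18 fits without 1 array, ZBTB33 lost its call in 11 (0.0532 to 0.0962), SLC2A5 in 9 (0.0515 to 0.0674), CBX3 in 8 (0.051 to 0.0664), EHMT1 in 4 (0.051 to 0.0644), HSPA9 in those without female bull 1 replicate 2 or female bull 3 replicate 3 (0.0514 and 0.0559), and BAK1 in that without male bull 2 replicate 2 (0.052).

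In the remaining lists, 0 of 6 pentose phosphate genes, 1 of 60 ribosomal protein genes (RPL29, -0.16) and 3 of 34 proteasome genes (PSMB5 -0.25, PSMB8 -0.26 and PSME2 -0.22) differed, all higher in males, and adjusted over the list alone these were 1, 0 and 3. Of 37 cell cycle genes 4 were higher in males, CCND2 (-0.29), MCM7, BUB1 and AURKB (3 adjusted over the list alone). Of 25 interferon-stimulated genes 5 were higher in females, among them IRF7 (0.36), and 1 in males (6 and 1 adjusted over the list alone). Of 21 growth factor genes TGFB1 (0.59) and VEGFA (0.29) were higher in females, and of 39 splicing genes 3 were higher in females and 2 in males, with CELF1 at 0.28 and HNRNPU at -0.26. Of markers of other cells, 5 of 26 cumulus and granulosa genes were higher in females and 1 in males, with TIMP2 at 0.70 and COL1A2 at -0.26. In blood cells 5 of 16 were higher in females and 1 in males (5 and 2 adjusted over the list alone), with HBB at 0.81 and CD68 at -0.43. Of 9 oocyte genes OOEP was higher in females (0.36), and of 13 sperm genes PRM1 and TNP1 were higher in females and ODF2 (-0.25) and SPA17 (-0.28) in males (2 and 3 adjusted over the list alone). Without 1 of the bulls RPL29, PSMB8, PSME2, CCND2, MCM7, BUB1, AURKB, VEGFA, CELF1, HNRNPU, COL1A2, HBB and OOEP lost their calls (adjusted p = 0.0551 to 0.285), as did RPL29, MCM7, BUB1, AURKB and HNRNPU with bull as the replicate (0.052 to 0.163), CELF1 and HBB without moderation (0.0778 and 0.0652), CELF1 with quantile normalization (0.0534), and HNRNPU without 4 arrays of wide spread (0.057). Of 18 fits without 1 array, AURKB lost its call in 16 (0.056 to 0.101), RPL29 in 13 (0.0517 to 0.0858), CELF1 in 11 (0.0522 to 0.0841), and COL1A2 in those without female bull 2 replicate 2 or male bull 2 replicate 2 (0.0551 and 0.0547).

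**Figure D3:**
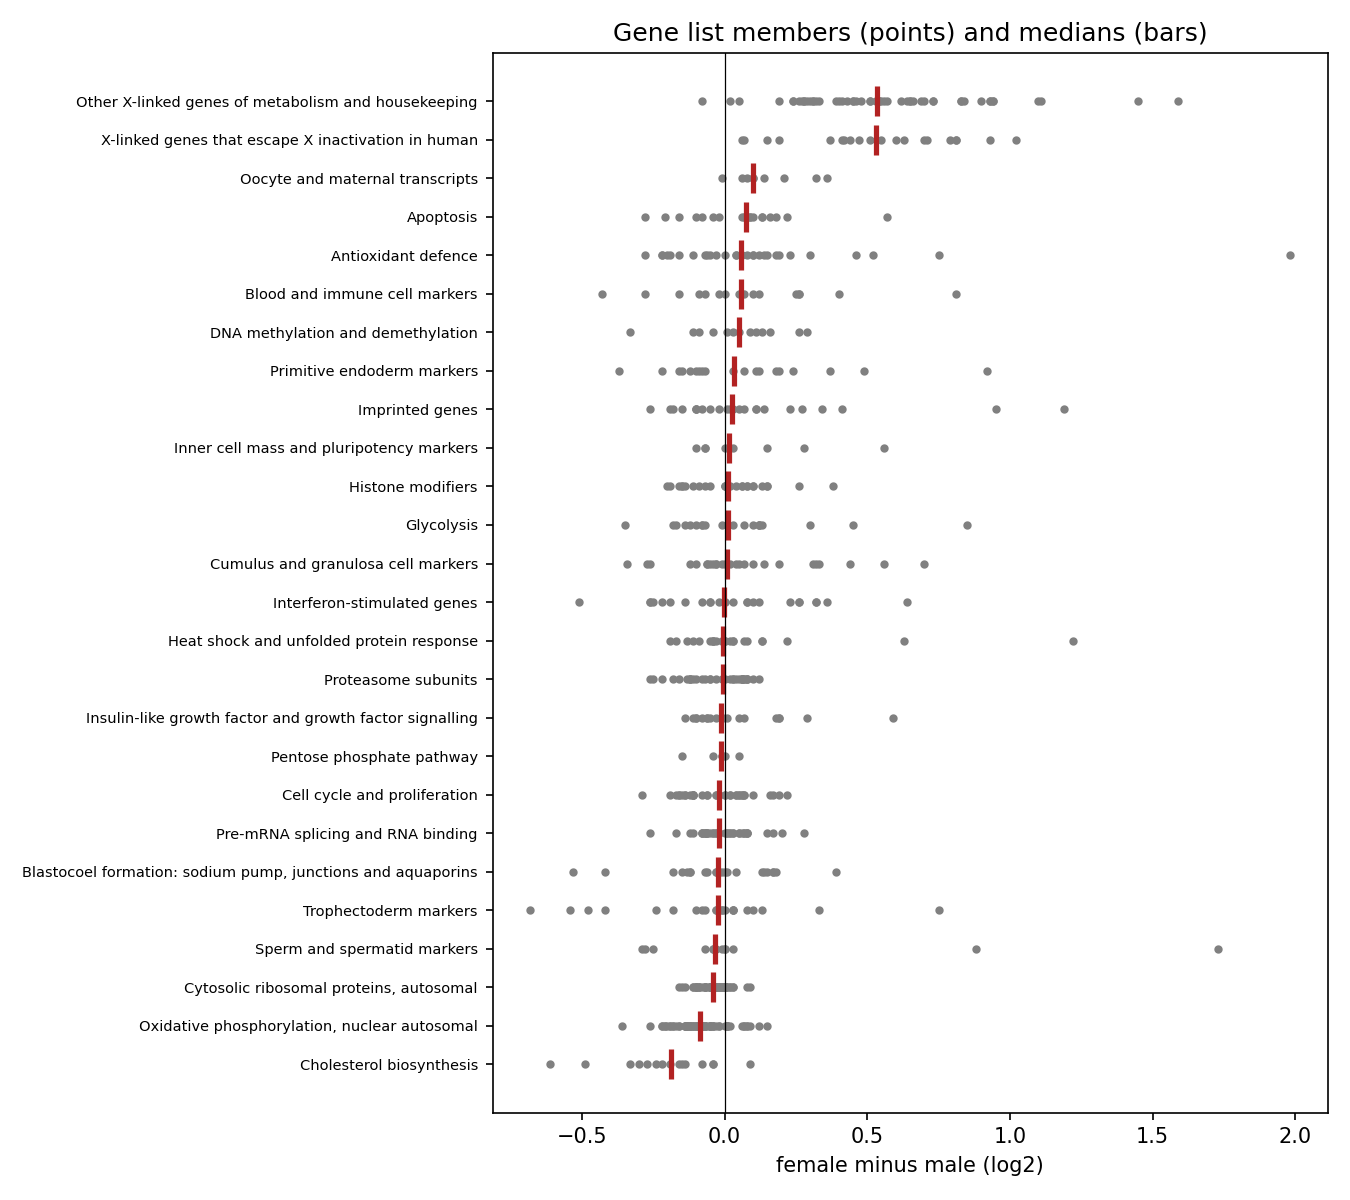
Female minus male difference (log2, horizontal axis) of each measured member of the 26 tested gene lists (grey points) with the list's median (red bar). The medians of both X-linked lists lie at 0.53, and that of cholesterol biosynthesis, the lowest, at -0.19.

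The bulls differed in single genes, and the rule for naming them required the same sign in both sexes. Each bull is a single sire, and arrays of a bull may share a production or scan batch that the labels do not give. A difference between bulls therefore cannot be told apart from such a batch. POSTN, periostin, stood at 5.70 ± 1.03 in bull 2 and 3.54 ± 0.96 in bull 1 (4.48-fold, SD, n = 6 arrays per bull), MT1A, a metallothionein, was 2.32-fold higher, ZNF79 2.18-fold and OLR1 2.37-fold, and GLRB, GZMB, S100A11 and CPE were lower by 2.60, 2.13, 2.02 and 1.92-fold. POSTN is among the 26 cumulus and granulosa markers, of which DCN was also higher in bull 2 than in bull 1 (0.84 log2, adjusted p = 0.0038), CYP19A1 was lower (-0.49, adjusted p = 0.03) and VIM did not pass (1.59, adjusted p = 0.1). That list had an adjusted p of 0.0614, and adjusted p = 0.939 with an estimated correlation. In bull 3 against bull 1, GSTO1, a glutathione transferase, stood at 8.99 ± 0.30 and 7.64 ± 0.30 (2.56-fold), SLC39A8, PPM1K and SIRPA were higher by 1.75, 1.72 and 1.68-fold, and CS, citrate synthase, TAT, CD2AP and GLRB were lower by 2.42, 2.38, 2.14 and 2.10-fold. In bull 3 against bull 2, MEST, SIRPA, GZMB and PPP1R1A were higher by 1.98, 1.95, 1.92 and 1.84-fold, and GNL1, HNRNPA0, ASPSCR1 and CLN3 lower by 2.62, 2.56, 2.44 and 2.23-fold. These were the probe sets with the largest differences, and the brightest one of a gene did not pass where it was another, at 0.06 log2 for CS, 0.11 for CD2AP, 0.35 for PPM1K and 0.06 for SIRPA against bull 1, and at 0.22 for MEST, -0.14 for SIRPA, 0.22 for GNL1, 0.10 for HNRNPA0, 0.19 for ASPSCR1 and -0.15 for CLN3 against bull 2. Another probe set passed in the same direction for PPM1K (0.65) and CD2AP (-0.66) against bull 1. The same held for SIRPA (0.40) and GNL1 (-0.50) against bull 2. The remaining probe sets of these genes did not pass. The F-test of limma over the 3 bulls called 1534 of 24016 probe sets (6.39%), and the pairs 364 (bull 2 against 1, 114 higher in bull 2), 848 (bull 3 against 1, 284 higher in bull 3) and 897 (bull 3 against 2, 406 higher in bull 3). Leaving out 1 array moved the count of the F-test to 670 to 2159 and those of the pairs to 133 to 607, 271 to 1594 and 384 to 1337. The lowest were those without female bull 3 replicate 1 (F-test and bull 3 against 1) and female bull 2 replicate 1 (both other pairs), and the highest those without male bull 3 replicate 2 (F-test and bull 3 against 1), male bull 1 replicate 3 (bull 2 against 1) and male bull 1 replicate 2 (bull 3 against 2).

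The mean 5′ minus 3′ signal of 3 housekeeping control transcripts was lowest in the groups of bull 3. It was measured on amplified RNA and is read here as a sign of RNA integrity. This index was -0.58 and -0.80 log2 in females and males of bull 3, -0.25 and -0.26 in those of bull 2, and -0.21 and 0.01 in those of bull 1. The GAPD and EF1A controls followed this order of bull 3 below the others, while the actin control did not, at -1.66 and -1.92 in bull 3, -1.74 and -1.80 in bull 2 and -1.98 and -1.40 in bull 1. Single arrays overlapped, with female bull 3 replicate 3 at -0.359 and female bull 1 replicate 2 at -0.441. With the index as a covariate, chosen after seeing the data, 12 probe sets differed between bulls 3 and 1 and 143 between bulls 3 and 2. Against bull 1, CS, CD2AP, GLRB, SIRPA, PPM1K and SLC39A8 then lost their calls, at -0.68, -0.21, -0.56, 0.53, 0.76 and 0.76 log2 (adjusted p = 0.151 to 0.963), while GSTO1 and TAT still passed. Against bull 2, GNL1, HNRNPA0, ASPSCR1 and CLN3 lost theirs, at -1.25, -1.07, -1.11 and -0.97 log2 (adjusted p = 0.0546 to 0.0762). CD2AP, POSTN, OLR1 and CPE lost their calls without moderation (adjusted p = 0.0591 to 0.0809) and without 4 arrays of wide spread (0.0525 to 0.127). POSTN, OLR1 and CPE lost their calls without male bull 2 replicate 1 (adjusted p = 0.0574, 0.0578 and 0.0584) and without female bull 2 replicate 1 (0.0558, 0.058 and 0.0544). POSTN also lost it without male bull 2 replicate 3 (0.0534), CPE without female bull 2 replicate 2 (0.0596), and both without female bull 1 replicate 3 (0.0527 and 0.0582).

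**Figure D4:**
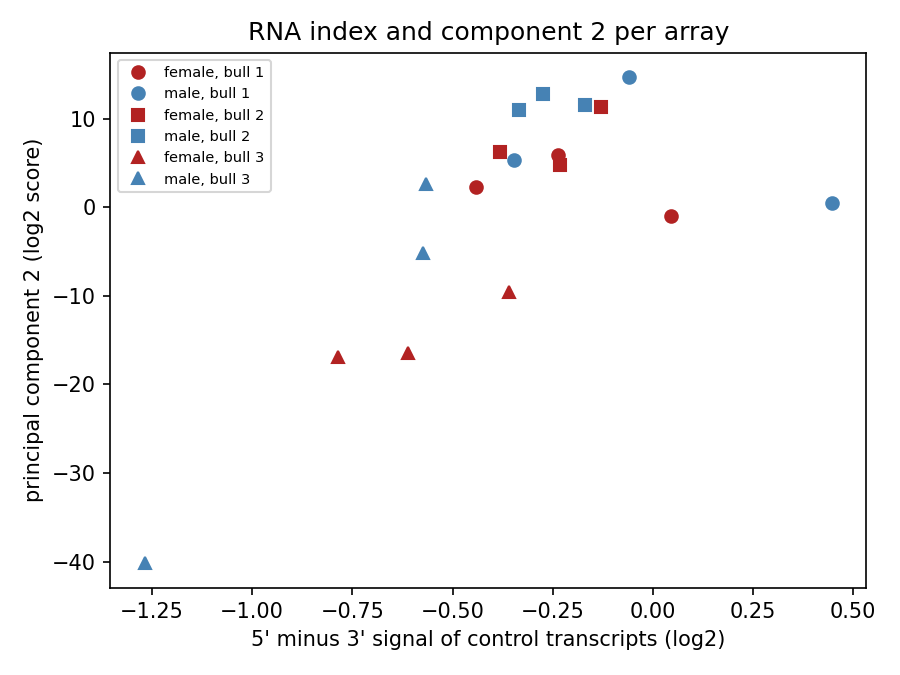
Mean 5′ minus 3′ signal of 3 control transcripts (log2, horizontal axis) against the score on principal component 2, which holds 16.4% of the variance (vertical axis), for each of the 18 arrays by sex and bull. The male bull 3 replicate 3 array lies apart, at -1.27 and -40.2.

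Of 78 tests of a list between 2 bulls, camera called 1, glycolysis, whose 20 genes had a median difference of -0.11 log2 between bull 3 and bull 2, with 5 of them above 0 (adjusted p = 0.0135, and adjusted p = 0.939 with an estimated correlation). The glucose transporter SLC2A3 (-0.83) and the lactate transporter SLC16A1 (-0.33) were lower, PFKM (0.52) was higher, and ENO1 (-0.41) did not pass. Adjusted over the list alone, 8 of the 20 differed. The 5′ to 3′ index differed by -0.441 log2 between these bulls, and with it as a covariate the list's mean was -0.052 in place of -0.136 and its call was lost (adjusted p = 0.281). The call was also lost with quantile normalization (adjusted p = 0.0967), without 4 arrays of wide spread (0.117) and without female bull 2 replicate 1 (0.0719). Other settings called more lists between the bulls, 5 with the mean over the probe sets of a gene, 6 without female bull 1 replicate 3 or male bull 1 replicate 3, 4 without male bull 2 replicate 2, and 3 without female bull 2 replicate 2, male bull 3 replicate 2 or male bull 3 replicate 3. In fry's test 1 passed, heat shock, with a median of -0.081 log2 in bull 3 against bull 1 (adjusted p = 0.0335), where the index differed by -0.596 log2, and camera did not call it (adjusted p = 0.101, and adjusted p = 0.939 with an estimated correlation). In 85 of 100 splits of the arrays, the real one included, at least 1 list passed camera's test.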

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

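The tests of a single array, of sperm RNA, of the autosomal calls, of the reassigned index and of the ranked X-linked share were chosen after the results were seen, as were the alternatives with the 5′ to 3′ index and without 4 arrays, and the count for bull 3 with the index was known before the test of signs. The tests of lists for a sex difference that differed between bulls were not among those planned. The following gene lists passed in camera's test with the preset correlation, and each of them lost its call with an estimated correlation (adjusted p = 0.936). Against bull 1, the sex difference in bull 3 was shifted by a median of 0.154 log2 for oxidative phosphorylation, 0.082 for ribosomal proteins, 0.13 for the proteasome, 0.45 for oocyte transcripts, -0.083 for blastocoel formation and -0.051 for heat shock. Against bull 2, it was shifted by 0.101 for oxidative phosphorylation and 0.069 for ribosomal proteins. In oxidative phosphorylation the median sex difference was -0.162, -0.102 and 0.011 log2 in bulls 1, 2 and 3, and the index of females minus males was -0.22, 0.01 and 0.22 log2 there. The medians of the other lists also followed the order of the index over the bulls, upward or downward. This order is no evidence on RNA integrity. The lists were picked for a difference between bull 3 and bull 1, so only the place of bull 2 was free. The index gaps in bulls 1 and 3 also rest on 1 male array each, male bull 1 replicate 2 (0.447) and male bull 3 replicate 3 (-1.268). For single probe sets no interaction was called, so that all 100 splits of the arrays reach the count of 0 by construction and tell nothing about chance, with 25 as the highest.

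Chance can be excluded for the sex difference, since 1 of 100 splits of sex within bulls, the real one, gave 3743 probe sets and the highest other 1, but the odds ratio of the X chromosome among calls (20.93, 1 of 100) cannot be set against the other splits, which had no call toward females on the X chromosome or autosomes to compute it from. Among the 1241 X-linked or autosomal probe sets ranked highest toward one side in each split, taking the side with the larger odds ratio and needing no call, chance can be excluded for the odds ratio (1 of 100, 20.93 against at most 16.18). It can also be excluded for the F-test of the bulls (1 of 100, 1534 against at most 2) and for bull 2 against 1 (364 against at most 32), bull 3 against 1 (848 against 1) and bull 3 against 2 (897 against 2). These splits treat arrays as exchangeable between bulls, so a batch shared by the arrays of 1 bull is not excluded. Chance cannot be excluded for the number of lists by sex (55 of 100 splits, 4 against up to 9) or by bull (85 of 100, 1 against up to 19). Why some splits called more lists than the real one was not tested. Within bulls, 10 splits are too few for a share under 0.05, with 1008 against at most 2, 752 against 0 and 1004 against 1.

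Bull 3 differed from bull 1 at 848 probe sets, and its groups had the lowest mean 5′ to 3′ index, though not for the actin control. The trend with the index inside groups gave the sign of the bull difference for 85.6% of these probe sets, against 67% of all probe sets, 71% of the calls of bull 3 against 2, and 71.7% of those of bull 2 against 1, where the index differed by -0.155 log2. With the index reassigned among the arrays of each group, 4 of 100 assignments, the real one included, gave as high a share, with the others from 15.2% to 88.2%. The arrays of lowest and highest index, male bull 3 replicate 3 (-1.268) and male bull 1 replicate 2 (0.447), also had the widest relative spread (0.349 and 0.335). Their deviations enter both the trend and the means of their bulls, so the real assignment could give a high share for this reason alone. The share was not computed without them. RNA integrity stays a candidate explanation for part of the pattern, which these signs do not settle. With the index as a covariate the median absolute difference fell from 0.432 to 0.254 log2 while its median error rose from 0.096 to 0.125, and 12 probe sets were called, 11 of them among the 848. The array male bull 3 replicate 3 is argued against as the whole cause, since 400 probe sets passed without it, and a difference between the bulls themselves stays open, because the index and the bull move together.

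Of autosomal probe sets 2067 differed between the sexes. The index of females minus males was -0.22, 0.01 and 0.22 log2 in bulls 1, 2 and 3. The gaps in bulls 1 and 3 rest on 1 male array each. Male bull 1 replicate 2 stood at 0.447, the other males there at -0.347 and -0.06, and the female mean at -0.21. Male bull 3 replicate 3 stood at -1.268, the other males there at -0.575 and -0.566, and the female mean at -0.585. Of the autosomal calls made from the 6 arrays of bull 1 (123) or bull 3 (256) alone, 98.7% had the same sign in the other bull. This share does not decide on RNA integrity, because the opposite gaps depend on these single arrays. The 4 arrays of wide spread are argued against as the cause by 86.8% being kept without them. Sex itself, and anything else that differs between sorted semen fractions, stays open and was not tested.

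PRM1 and TNP1, transcripts of maturing sperm, were higher in females by 1.73 and 0.88 log2. The median difference of 11 other sperm transcripts was -0.039 log2, which decides nothing, because the levels of these transcripts in sperm are not in these data and the rise that carried RNA would give each is unknown. Sperm RNA in the female pools, expression in the embryo and probes that also bind another transcript stay open, and probe sequences were not used here.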

How the results depend on the processing

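The settings without 4 arrays of wide spread and with the 5′ to 3′ index were added after seeing the data. The interaction count was 0 in every setting run, and the odds ratio of the X chromosome kept its direction and its call, from 15.61 with array weights to 52.38 in the brighter 50% of probe sets. Of the named genes and lists no call reversed, but 47 of 113 named sex genes and 13 of 24 named bull genes lost a call in at least 1 setting. Of the sex genes 23, 33 and 31 lost it without bulls 1, 2 and 3, 16 with bull as the replicate, 7 without moderation, 7 without 4 arrays, and 15 without some single array (123 of 2034 fits). The cause of the changes below was not tested, except where fewer probe sets or arrays were used. With 1 probe set per gene, 2222 (1173 higher in females, 1049 in males) differed by sex, 761 by bull, 440 for bull 3 against 1 and 352 for bull 3 against 2. Array weights gave 2778 higher in males, 1740, 1799 and 3144 within bulls 1, 2 and 3, 3777 by bull, and 1161, 2045 and 2693 for bulls 2 against 1, 3 against 1 and 3 against 2. Without moderation 831 differed by bull, 459 for 3 against 1 and 555 for 3 against 2. The brighter 50% gave 569 for bull 2 against 1. Without bull 1, 1193 were higher in males. Without bull 2, 2044 differed by sex (1145 and 899), and without bull 3, 2182 (843 higher in males). The arrays of 1 bull alone gave 290 for bull 1 and 596 for bull 3.

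The lists called were 2 by sex and 0 by bull with an estimated correlation, and by bull 0 with quantile normalization and 5 with the mean over probe sets. Without the 4 arrays, 1130 and 1545 differed within bulls 2 and 3, 228 for bull 2 against 1, 466 for 3 against 1, and 0 lists by bull. With the index 358 differed by bull, 12 for 3 against 1, 143 for 3 against 2, and 0 lists by bull.

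Sample numbers gave no sign of pairing between female and male arrays of a bull. The labels do not say whether the numbers mark a shared run or day, and numbers shared between bulls were not checked. Deviations of the 9 same-numbered pairs correlated between -0.181 and 0.103, 2 of them over 0.1, and 2 of 9 female arrays correlated best with their own number. The replicate block was the number within each bull for tests of sex, and the number alone for tests of bull. With it 2977 probe sets differed by sex and 1164 by bull, 629 and 618 within bulls 1 and 3, and 2 lists by bull, with 515 in bull 2, and 17 named sex genes lost their calls.

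Leaving out 1 array gave 3175 to 3983 for sex (1731 to 2225 higher in females, 1439 to 1823 in males), and an odds ratio from 17.90 to 23.11 and 4 to 5 lists by sex. Within bulls the ranges were 625 to 1240, 422 to 956 and 465 to 1317, by bull 670 to 2159, for the pairs 133 to 607, 271 to 1594 and 384 to 1337, and for lists by bull 0 to 6. Writing F1-2 for female bull 1 replicate 2, counts moved by over 1.5 times without F1-1 (665) and F1-3 (625) in bull 1, F2-1 (474), F2-2 (422), F2-3 (474), M2-1 (478) and M2-2 (441) in bull 2, and F3-2 (522), F3-3 (465) and M3-1 (649) in bull 3. By bull they moved without F2-1 (769), F2-2 (860), F3-1 (670), F3-2 (709) and M2-1 (895). For 2 against 1 they moved without F1-3 (188), F2-1 (133), F2-2 (153), F2-3 (225), M1-3 (607), M2-1 (147), M2-3 (193) and M3-3 (577), for 3 against 1 without F1-1 (462), F1-3 (440), F3-1 (271), F3-2 (341), M3-2 (1594) and M3-3 (400), and for 3 against 2 without F2-1 (384), F2-2 (521), F3-1 (405), F3-2 (384), M2-1 (477) and M3-3 (545). Lists by bull were 0 without F2-1, 3 without F2-2, M3-2 and M3-3, 4 without M2-2, and 6 without F1-3 and M1-3. Dim probe sets near background limit what small differences can be seen.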

Other observations

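Of the probe sets with no gene listed, the 3 largest differences toward females, singled out after their values were seen, were 2.27, 2.03 and 1.55 log2, with the same direction in each bull. The excess of X-linked transcripts in females was present in each bull, with medians of 1.403, 1.493 and 1.477-fold among the brighter 50% of probe sets in bulls 1, 2 and 3, and no difference between bulls was tested for these medians. Among autosomes, chromosome 22 had 59 of 402 probe sets (14.7%) higher in males and 18 (4.5%) higher in females, and chromosome 9 had 15 of 273 (5.5%) and 32 (11.7%). These shares were not tested.

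CD99 was higher in males although it is listed on the X chromosome, and it lies in the pseudoautosomal region in human. A hypothesis is that genes shared by X and Y lack the female excess. A list of 31 other genes held those of the human region and X-linked genes next to it, whose place in cattle was not tested. Of these 3 were measured as X-linked, DHRSX (0.09 log2), ARSL (-0.09) and PUDP (0.19), and PUDP was higher in females (adjusted p = 0.0081). ARSL and PUDP lie outside the human region, and PUDP is also in the list of genes that escape X inactivation in human. The median of the 3 was 0.089 log2, against 0.442 for 292 other X-linked genes. An exact permutation test of the difference in medians, two-sided, gave p = 0.18. This test was chosen before it was run but after CD99 was seen, so it is not among those fixed before the data were examined. A rank-sum test run afterwards gave an exact p of 0.043, and since the 2 statistics differ over 3 genes the question stays undecided.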
